A study of Homo sapiens with 21 samples.

How the data were processed

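ES-4 tumors, a human Ewing sarcoma kept as a subcutaneous xenograft, were profiled by RNA sequencing. Per the labels, mice were randomized into groups of 10 when tumors measured 200 to 400 cubic mm. Eribulin was given intraperitoneally at 1 mg/kg on days 1 and 8 and irinotecan at 2.5 mg/kg on days 1 to 5, and a second round began on day 21. The sequenced tumors fell into 7 groups of 3 by label: untreated controls, and eribulin, irinotecan or both, harvested at 24 or 144 h. Per the series' design text the 3 tumors of a group came from 3 separate mice, so that the p-values measure the spread between mice. All 3 controls carried the 24 h label and 0 that of 144 h.

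Per the labels, RNA was extracted with TRIzol and a column kit with DNase treatment. Libraries came from a stranded mRNA kit, whose capture of histone transcripts without a poly(A) tail was not tested. Deposited values were whole-number read counts per gene symbol, not normalized, 1 table per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2, HTSeq, the human build hg19 and the mouse build mm9, with no role or order. Whether reads were counted by strand, and how reads from mouse cells in the tumors were handled, is not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as histones, tubulins, ribosomal proteins, the LCE1 family and CYP4F2 with CYP4F3, are therefore uncertain. Each table held 23228 genes and 5 summary lines of HTSeq for reads not given to a gene. These lines held 45.1% of all reads in the controls on average and stayed out of library sizes and tests.

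Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the deposited counts: TMM normalization, edgeR's default filter on low counts, and a quasi-likelihood F test over all 21 libraries with 1 coefficient per group. The filter left 15371 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. CPM are counts scaled to 1 M of the TMM-scaled library size. Gene counts summed to between 15.05 M and 35.0 M per library, both extremes in the irinotecan 144 h group, and the biological coefficient of variation was 12.4%. The 17 comparisons were each of the 6 treated groups against control, the combination against each drug and irinotecan against eribulin at each time, 144 h against 24 h for each treatment, and, at each time, the combination minus both single-drug effects. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.45, so that none was counted as 1 sample. The random seed was 20.

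The named genes were chosen by a fixed rule. Against control these were the 4 genes with the largest rise and the 4 with the largest fall that passed the threshold, had a mean log2 CPM of at least 1 and had all 3 treated libraries beyond all 3 controls, without pseudogenes and unnamed loci; the 3 members with the smallest p of the p53, mitosis, tubulin and EWS-FLI1 activated lists; the 2 members with the smallest p of every other list that camera called; and CDKN1A, MDM2, TOP1, SLFN11, ABCB1, CES2, TUBB3 and MKI67. In the other comparisons the 3 largest changes each way and the members of called lists were taken. The text prints part of the genes the rule named.

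Of 28 gene lists fixed before the data were examined, 26 had at least 3 tested members. They were p53 targets, mitosis, S-phase, replication-dependent histone, DNA repair, tubulin, interferon response, NF-kB and inflammatory, integrated stress and unfolded protein response, hypoxia, cholesterol synthesis, EWS-FLI1 activated, EWS-FLI1 repressed, mesenchymal, neural differentiation, apoptosis, and drug target and handling genes; markers of macrophages, neutrophils, endothelium, fibroblasts and pericytes, skeletal muscle, adipocytes and keratinocytes; and immediate-early and ribosomal protein genes as signs of RNA handling and quality. Of 8 erythroid markers 0 passed the filter, and 13 mitochondrially encoded genes were not used here. Of 20 macrophage, 13 neutrophil and 12 keratinocyte markers, 10, 5 and 6 passed it. The filter admits a marker nearly silent in controls only through higher counts in treated groups. How many tested markers rose, and the list calls on them, are therefore partly fixed by the filter. Lists were tested with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were the alternatives.

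A gene with 0 control counts over the group is given as at least N-fold higher against a floor of 3 counts, and a gene with 1 to 3 counts as a ratio with its exact 95% interval, which covers counting error only. Gene names of 21834 symbols matched a RefSeq table of another human build, used for names, gene types and the exclusion of pseudogenes. Gene lengths, from start to end of each gene, came from a GENCODE annotation, also of another build. The gene test, the list test and the length correlation were tested on simulated data drawn from the real means and library sizes. For eribulin at 24 h against control the test recovered 63.6%, 79.1% and 89.4% of genes changed 1.5-, 2- and 4-fold, the 1.5-fold genes including the mitosis list, with 1.69% of calls false. For eribulin at 24 h a simulated 1.5-fold rise of the mitosis genes was the only 1 of 26 lists called.

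The alternatives were DESeq2 1.42.0, DESeq2's size factors or library size alone in edgeR, no filter on low counts (20305 genes with at least 1 count), only the groups compared, the replicate number as a block, leaving out each library in turn, a 2-fold minimum for overlaps, and a mean log2 CPM of at least 3 for gene length. Covariances of fold changes over genes with a mean log2 CPM of at least 3, and sums over all genes with at most 3 counts in a group, were chosen after seeing the data. Overlaps were set beside 20 simulated data sets of unchanged groups against the same controls. The 6 libraries of a comparison of 2 groups allow 10 splits, and 50 were drawn for the 12 libraries of a non-additivity contrast.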

Results

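Transcript levels were measured by RNA sequencing in ES-4, a Ewing sarcoma grown as a subcutaneous xenograft in immune-deficient scid mice. Ewing sarcoma is a pediatric bone and soft tissue tumor driven in most cases by the EWS-FLI1 fusion. The tumors received eribulin, a microtubule inhibitor that blocks mitosis, irinotecan, a prodrug whose active form traps topoisomerase I on DNA, or both, and were harvested at 24 or 144 h. The 21 libraries formed 7 groups of 3 tumors, each from a separate mouse: controls, and each treatment at both times. All 3 control tumors carried the 24 h harvest label, so that every comparison of a 144 h group with control also held any change of the tumors between those times.

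**Figure D1:**
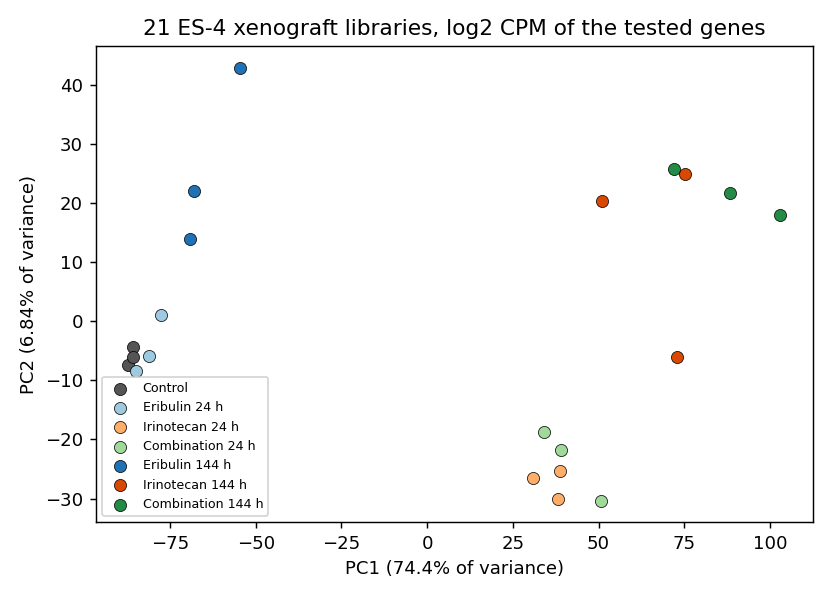
Principal components 1 (74.4% of variance) and 2 (6.84% of variance) of log2 CPM (counts scaled to a common library size) over the tested genes, 1 point per library and 1 color per group. The libraries given irinotecan, alone or with eribulin, lie on the right and the control and eribulin libraries on the left.

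Eribulin alone at 24 h raised a set of p53 targets, mitosis genes and histone genes in the tumors. CDKN1A, which encodes the cell cycle inhibitor p21, stood at 182 ± 70.9 CPM (SD, n = 3) against 35.9 ± 6.72 in controls, a log2 fold change of 2.34 (SE 0.24). PVRL4, which encodes the adhesion protein nectin-4, rose by 3.49 on the log2 scale (SE 0.45) from a control level of 0.656 ± 0.17 CPM. PTTG1, which encodes securin, the guard of sister chromatid cohesion, rose by 0.84 (SE 0.13), and the linker histone gene HIST1H1C rose from 23.2 ± 3.04 to 80.7 ± 22.1 CPM. The adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 6.28e-05 for CDKN1A, 0.000538 for PVRL4, 0.0031 for PTTG1 and 0.000259 for HIST1H1C.

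Of 35 p53 targets tested, 13 rose after 24 h of eribulin (24 adjusted over the list alone) and the others did not pass the test. Among them were TP53INP1, a proapoptotic stress protein gene, with a log2 fold change of 1.13, and C12orf5, which encodes the glycolysis regulator TIGAR, also with 1.13. Camera's list test gave an adjusted p = 6.94e-45 for the p53 targets (adjusted p = 0.0371 with an estimated correlation). Of 32 mitosis genes, 15 rose (25 adjusted over the list alone), among them CDC20, an activator of the anaphase-promoting complex, at 310 ± 43.8 against 152 ± 5.48 CPM, and the cyclin gene CCNB2. The list call of the mitosis genes (camera adjusted p = 5.93e-37) was lost with adjusted p = 0.0573 with an estimated correlation, and the edgeR calls of CDC20 and CCNB2 were lost without control replicate 2 (adjusted p = 0.0602 and 0.0754). Of 16 replication-dependent histone genes, 7 rose (12 adjusted over the list alone), HIST1H4H by 2.53 on the log2 scale among them (camera adjusted p = 3.16e-24, and adjusted p = 0.00552 with an estimated correlation). The S-phase list, with a median of −0.11, and the hypoxia list, with −0.14, were called lower by camera although no member passed edgeR's test, and had adjusted p = 0.66 with an estimated correlation each; the first call was lost without eribulin 24 h replicate 2 (adjusted p = 0.382), the second without control replicates 1 or 3 or eribulin 24 h replicates 1 or 3 (0.0575, 0.310, 0.0865 and 0.566). MKI67, the proliferation marker, was at 760 ± 80.0 against 653 ± 20.6 CPM and did not pass the test.

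Camera also called the ribosomal protein genes after 24 h of eribulin, with a median log2 fold change of 0.20 over 24 genes, none of which passed the edgeR test one by one, and 12 skeletal muscle markers as lower, with a median of −0.27 and no member past that test (1 adjusted over the list alone). Both calls were lost with adjusted p = 0.441 with an estimated correlation. Of 15 fibroblast and pericyte markers, COL1A2, a type I collagen gene, fell by 0.63 on the log2 scale (SE 0.11). The camera call of these markers was lost with adjusted p = 0.0687 with an estimated correlation, and the edgeR call of COL1A2 was lost without control replicate 2, control replicate 3 or eribulin 24 h replicate 1 (adjusted p = 0.0602, 0.0711 and 0.0516). MDM2, which encodes the ubiquitin ligase that degrades p53, was at 129 ± 20.2 against 76.5 ± 0.836 CPM, and its call was lost without control replicates 1, 2 or 3 or eribulin 24 h replicate 3 (edgeR adjusted p = 0.0700, 0.0873, 0.0824 and 0.0941). In all, 109 genes were higher and 12 lower of 15371 tested. Leaving out 1 library moved the number of higher genes to 43, 11 and 31 without control replicates 1, 2 and 3, and to 68 and 38 without eribulin 24 h replicates 1 and 3. The lower genes then numbered 2, 0, 0, 7 and 3 in edgeR, beside 94 lower and 281 higher genes in DESeq2 with all libraries, 271 and 502 in a fit of only the groups compared and 2144 genes at an unadjusted edgeR p under 0.05.

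**Figure D2:**
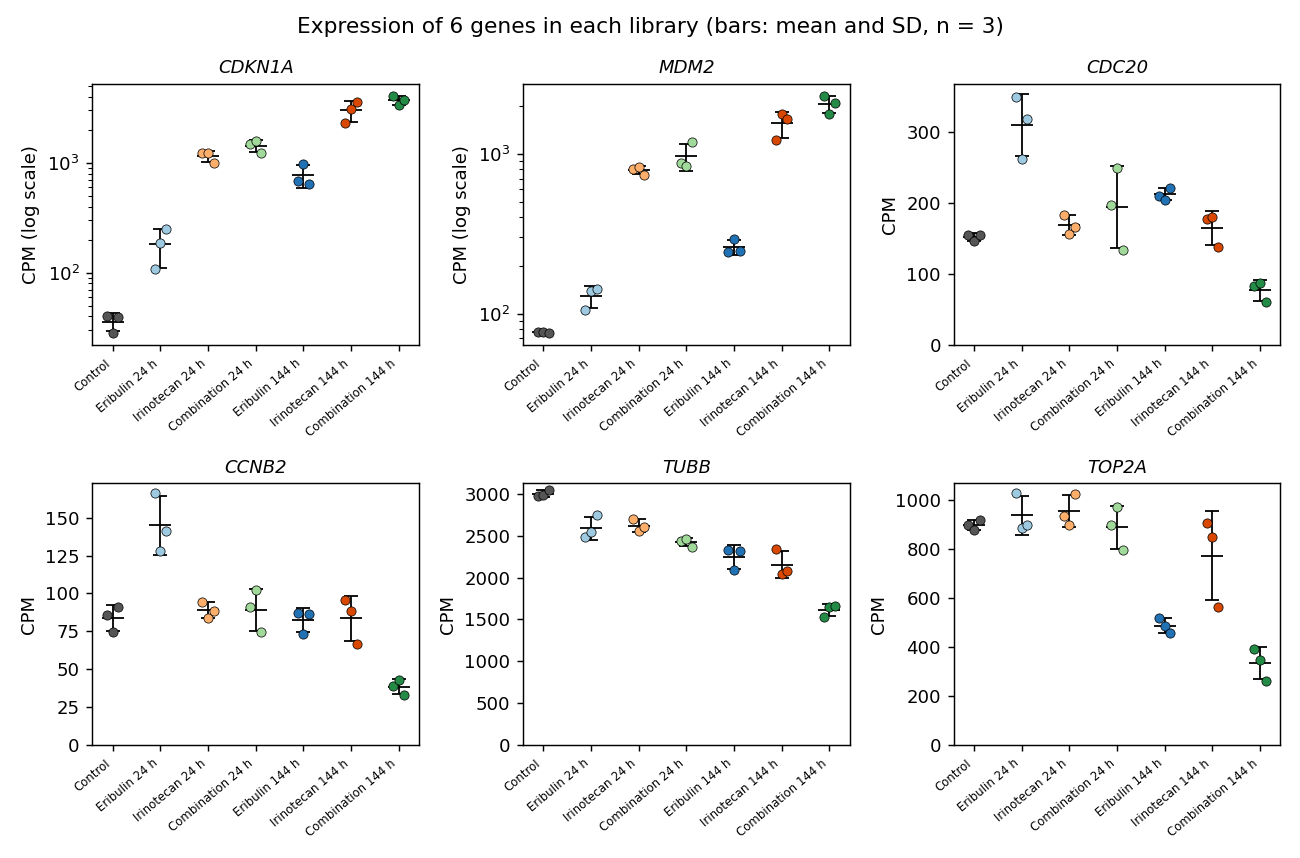
CPM of 6 genes in each library, with the 7 groups on the horizontal axis, points for single libraries, and bars for mean and SD (n = 3); the axes of CDKN1A and MDM2 are logarithmic. CDKN1A averages 35.9 CPM in controls, 182 after 24 h of eribulin and 3737 after 144 h of both drugs.

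Irinotecan alone at 24 h raised every one of the 35 p53 targets, 12 NF-kB and inflammatory genes and many genes that the control tumors hardly expressed. CDKN1A reached 1155 ± 129 CPM (SD, n = 3) against 35.9 ± 6.72, a log2 fold change of 5.01 (SE 0.27). GADD45A, a growth arrest and DNA damage gene, rose by 5.34 (SE 0.25), MDM2 by 3.37 (SE 0.16) and DRAM1, an autophagy regulator, by 5.39 (SE 0.26). LIF, a cytokine of the interleukin-6 family, rose from 3.68 ± 0.294 to 237.7 ± 24.3 CPM, and IL8, a neutrophil-attracting chemokine gene, from 1.23 ± 0.0714 to 152 ± 18.1 CPM. The adjusted p in edgeR's test with Benjamini-Hochberg adjustment was 1.41e-11 for CDKN1A, 2.18e-12 for both GADD45A and LIF, 2.53e-12 for MDM2 and 4.86e-10 for IL8.

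The largest rises at 24 h of irinotecan were in genes with almost no control reads. CYP4F3, a leukotriene omega-hydroxylase gene, had 1942 counts over the 3 treated libraries and 1 over the controls, a ratio of 1785 (exact 95% interval 320 to 70529). SEMA3E, a semaphorin gene, had 2168 counts against 2, a ratio of 996 (275 to 8231). LCE1C, of the late cornified envelope family of the epidermis, had 1217 against 1, a ratio of 1119 (200.4 to 44212), and CYP4F2 had 1246 against 1. CYP4F2 and CYP4F3, and the members of the LCE1 family, are close copies of each other, and how reads were split between them is uncertain. Over all 23228 genes, the 7284 with at most 3 counts over the controls summed to 1043 ± 68.2 CPM with irinotecan against 42.7 ± 2.51 in controls (SD, n = 3). The 6161 with at most 3 counts over the irinotecan libraries summed to 37.6 ± 1.87 there and 36.4 ± 2.30 in controls, and 390 olfactory receptor genes to 15.99 ± 1.94 with irinotecan and 6.36 ± 0.793 in controls. In the other direction CAMK2B, a calmodulin-dependent kinase gene, fell by 1.17 on the log2 scale (SE 0.30). SYK, a tyrosine kinase gene, fell by 1.93, a call lost without control replicate 2, control replicate 3 or irinotecan 24 h replicate 2 (edgeR adjusted p = 0.0592, 0.0508 and 0.0684).

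By list, all 35 p53 targets rose at 24 h of irinotecan, with a median log2 fold change of 2.61 (camera adjusted p = 1.74e-106, and adjusted p = 0.00178 with an estimated correlation). Of 20 NF-kB and inflammatory genes 12 rose (12 adjusted over the list alone), with adjusted p = 0.172 with an estimated correlation. Of 24 cholesterol synthesis genes 13 fell and 2 rose (16 and 2 adjusted over the list alone), and the list call was lost with adjusted p = 0.467 with an estimated correlation. The genes that rose were HSD17B7, of the late sterol pathway, by 1.33, and STARD4, a sterol carrier gene, by 1.17. Mitosis genes were nearly flat: TPX2, a spindle assembly factor gene, was the only one of 32 to pass, with 0.50, and MKI67 had 0.04. Of 16 histone genes 3 fell, of 32 S-phase genes 1 rose and 1 fell, and of 28 DNA repair genes 1 rose. Of 11 tubulin genes TUBA4A rose by 0.68, while TUBB at −0.20 and TUBB3 at −0.35 did not pass.

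Among the remaining lists at 24 h of irinotecan, 5 of 24 EWS-FLI1 activated genes rose and 5 fell. UPP1, a uridine phosphorylase gene, was up by 1.08 and SOX2, a transcription factor gene of stem cells, up by 1.45. Of 13 EWS-FLI1 repressed genes 6 rose and 1 fell, of 20 mesenchymal genes 5 rose and 3 fell, and of 21 neural differentiation genes 9 rose and 2 fell. Of 22 apoptosis regulators 8 rose and 1 fell, of 21 integrated stress and unfolded protein response genes 5 rose and 2 fell, of 24 hypoxia genes 1 rose and 1 fell, and of 30 interferon response genes 3 rose. Of 10 drug target and drug handling genes 3 rose and 1 fell. TOP1, the target of irinotecan, rose by 0.50 (SE 0.10), CES2, a carboxylesterase gene whose product activates irinotecan, by 1.22 (SE 0.11), and ABCB1, a drug efflux pump gene, rose from 0.0725 ± 0.0857 to 4.59 ± 0.483 CPM. SLFN11, whose product blocks stressed replication, had −0.14 and did not pass.

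Markers of other cell types moved beside these genes. Of 10 macrophage markers 4 rose, among them the integrin gene ITGAM, from 0.718 ± 0.16 to 210 ± 33.4 CPM, and the lysosomal gene LAPTM5, and the list call was lost with adjusted p = 0.124 with an estimated correlation. All 6 keratinocyte markers tested rose, with FLG, the filaggrin gene, at least 30.3-fold higher (0 against 99 counts, floor of 3 counts over the group), and the list call was lost with adjusted p = 0.172 with an estimated correlation. Of 12 skeletal muscle markers 7 rose, of 11 endothelial markers 5 rose and 1 fell, of 15 fibroblast and pericyte markers 2 rose and 2 fell, of 6 adipocyte markers 3 rose and of 5 neutrophil markers 2 rose. Of 11 immediate-early genes, a sign of RNA handling, 3 rose. Of 24 ribosomal protein genes 2 fell, and the list call was lost without irinotecan 24 h replicate 1 (camera adjusted p = 0.105) and with adjusted p = 0.765 with an estimated correlation. In all, 2918 genes rose and 939 fell. The lower genes numbered 448, 377 and 389 without control replicates 1, 2 and 3, and 618 and 524 without irinotecan 24 h replicates 1 and 2, and were 2492 in a fit of only the groups compared.

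With both drugs at 24 h, CDKN1A was at 1432 ± 176 CPM (SD, n = 3), MDM2 at 968 ± 190 against 76.5 ± 0.836 in controls and GADD45A at 493 ± 78.3 against 10.0 ± 0.586. In edgeR's test with Benjamini-Hochberg adjustment the log2 fold changes were 5.32 (SE 0.27, adjusted p = 5.98e-12), 3.66 (SE 0.16, adjusted p = 1.27e-12) and 5.62 (SE 0.25, adjusted p = 1.37e-12). All 35 p53 targets rose, with a median of 2.73 (camera adjusted p = 2.13e-100, and adjusted p = 0.00241 with an estimated correlation). CYP4F3 had 1960 counts against 1 (ratio 2079, exact 95% interval 373 to 82171). The 7284 genes nearly silent in controls summed to 1162 ± 249 CPM against 42.7 ± 2.51.

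In the combination at 24 h, 12 of 20 NF-kB and inflammatory genes rose (15 adjusted over the list alone), LIF by 6.12 and the NF-kB subunit gene RELB by 4.04, with adjusted p = 0.28 with an estimated correlation. Of 24 cholesterol synthesis genes 12 fell and 2 rose (15 and 2 adjusted over the list alone), with adjusted p = 0.485 with an estimated correlation. Of 11 tubulin genes 3 fell, TUBA1A by 0.44 and TUBB by 0.31 on the log2 scale among them, as did TUBA1B, whose call was lost without control replicate 1, control replicate 3 or combination 24 h replicate 3 (edgeR adjusted p = 0.0505, 0.0989 and 0.0591). Of 32 mitosis genes 3 rose (1 adjusted over the list alone): TPX2 by 0.62, and AURKA and UBE2C, which were each lost without several single libraries, control replicates 2 and 3 among them (edgeR adjusted p = 0.0979 and 0.0761 for AURKA, 0.0869 and 0.0767 for UBE2C). AURKA was also lost in a fit of only the groups compared (0.0511), UBE2C without control replicate 1 (0.0583), and both without combination 24 h replicates 1 (AURKA 0.122, UBE2C 0.124) and 2 (AURKA 0.203, UBE2C 0.213). Of 21 neural differentiation genes 9 rose and 2 fell, STMN4, a stathmin family gene of neurons, by 5.48, with adjusted p = 0.195 with an estimated correlation. MYC, listed with the EWS-FLI1 activated genes, of which 7 rose and 6 fell, fell by 0.45. TOP1 rose by 0.61, CES2 by 1.37 and ABCB1 by 6.02, while SLFN11 at −0.21, TUBB3 at −0.26 and MKI67 at 0.12 did not pass.

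Beside these, 4 of 10 macrophage markers and all 6 keratinocyte markers rose, with ITGAM at 216 ± 53.9 CPM and FLG at least 32.5-fold higher. Skeletal muscle (7 of 12), endothelial (5 of 11), adipocyte (3 of 6) and neutrophil markers (2 of 5) rose in part, with no camera call of these lists (adjusted p = 0.340, 0.462, 0.106 and 0.106). The list calls were lost with adjusted p = 0.0907 with an estimated correlation for the macrophage and adjusted p = 0.195 with an estimated correlation for the keratinocyte markers. Of 24 ribosomal protein genes 15 fell (15 adjusted over the list alone), with adjusted p = 0.549 with an estimated correlation. Of 24 hypoxia genes 7 fell and 1 rose, and the list call was lost without control replicate 3 or combination 24 h replicate 2 or 3 (camera adjusted p = 0.0695, 0.0628 and 0.120) and with adjusted p = 0.655 with an estimated correlation. The combination at 24 h raised 3277 genes and lowered 1572. The lower genes numbered 899, 815 and 816 without control replicates 1, 2 and 3, and 1038 without combination 24 h replicate 3, and were 2811 in a fit of only the groups compared.

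After 144 h of eribulin alone the tumors had high p53 targets, low S-phase, DNA repair and cholesterol synthesis genes, and low TOP2A and MKI67. CDKN1A was at 775 ± 185 CPM (SD, n = 3) against 35.9 ± 6.72 in the 24 h controls, a log2 fold change of 4.43 (SE 0.26), and TP53INP1 at 78.3 ± 9.57 against 12.9 ± 1.49. TOP2A, which encodes topoisomerase II alpha, fell to 487 ± 31.1 from 898 ± 19.9 and the replication helicase gene MCM3 to 203 ± 13.2 from 345 ± 9.92. The adjusted p in edgeR's test with Benjamini-Hochberg adjustment was 1.18e-09 for CDKN1A, 2.77e-10 for TP53INP1, 0.000406 for TOP2A and 5.49e-06 for MCM3.

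Of 35 p53 targets 34 rose at 144 h of eribulin (34 adjusted over the list alone), with a median of 1.49, and of 32 S-phase genes 27 fell (29 adjusted over the list alone), with a median of −0.70. Of 28 DNA repair genes 19 fell (22 adjusted over the list alone), FANCI and FANCA of the Fanconi anemia pathway by 0.84 and 0.74 on the log2 scale among them. Of 24 cholesterol synthesis genes 17 fell (20 adjusted over the list alone, and 1 rose there), FDFT1, the squalene synthase gene, by 0.98. Camera gave an adjusted p = 6.51e-114, 4.5e-41, 4.12e-20 and 8.55e-29 for these 4 lists, and with estimated correlations adjusted p = 0.00119, 0.0178, 0.0178 and 0.00372. Of 32 mitosis genes 12 fell (16 adjusted over the list alone, and 1 rose there), the kinesin gene KIF11 by 0.59 among them, with adjusted p = 0.33 with an estimated correlation. MKI67 fell by 0.70 on the log2 scale (SE 0.16). Of 16 histone genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), HIST1H1C by 1.58, with adjusted p = 0.182 with an estimated correlation.

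Of 11 tubulin genes at 144 h of eribulin, TUBA1B fell by 0.48 and TUBB by 0.42 on the log2 scale, 2 rose, and TUBB3 at 0.35 did not pass. The rise of TUBB4, by 0.51, was lost without control replicate 3 (edgeR adjusted p = 0.0619). Of 30 interferon response genes 9 rose (13 adjusted over the list alone), IFI27 by 1.31 and ISG15 by 1.29, and of 20 NF-kB and inflammatory genes 5 rose (8 adjusted over the list alone), LIF by 2.76. These calls were lost with adjusted p = 0.368 with an estimated correlation for the interferon list and adjusted p = 0.245 with an estimated correlation for the NF-kB list. PVRL4 rose by 4.89 (SE 0.42) and GDF15, a stress cytokine gene and p53 target, by 4.77 (SE 0.43), to 99.5 ± 79.0 CPM. Of 24 EWS-FLI1 activated genes 4 rose and 1 fell, with CCK, the cholecystokinin gene, up by 0.84, UPP1 up by 1.00 and MYBL2, a cell cycle transcription factor gene, down, with −0.51. CES2 rose by 0.80, while TOP1 at −0.04, SLFN11 at −0.22 and ABCB1 at 0.49 did not pass.

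Beside these, 3 of 10 macrophage markers rose, CD68 by 1.27 and ITGAM to 3.39 ± 1.68 CPM, 2 of 6 adipocyte markers rose, with PLIN4 up by 2.13, and 1 of 6 keratinocyte markers, KRT10, rose by 0.64. The calls of these 3 lists were lost with adjusted p = 0.159, 0.182 and 0.226 with an estimated correlation. Of 15 fibroblast and pericyte markers 4 fell, COL1A2 by 0.48 on the log2 scale, a list call lost without control replicate 3 (camera adjusted p = 0.0560) and with adjusted p = 0.183 with an estimated correlation. Of 11 immediate-early genes 5 rose (10 adjusted over the list alone), with adjusted p = 0.226 with an estimated correlation. In all, 1158 genes rose and 979 fell. The higher genes numbered 687, 581 and 619 without control replicates 1, 2 and 3 and 704 without eribulin 144 h replicate 2, and the lower genes 553 and 562 without control replicates 2 and 3.

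Irinotecan alone at 144 h left all 35 p53 targets, all 20 NF-kB and inflammatory genes and 26 of 30 interferon response genes higher than in the controls. CDKN1A was at 3003 ± 652 CPM (SD, n = 3), MDM2 at 1549 ± 287 and GADD45A at 748 ± 242, with log2 fold changes of 6.39 (SE 0.28), 4.34 (SE 0.16) and 6.22 (SE 0.26). LIF was at 392 ± 64.8 CPM, a rise of 6.74, RELB rose by 4.28, and the interferon-induced genes EPSTI1 and IFI27 by 3.82 and 2.23. In the other direction ARHGAP28, a GTPase activating protein gene, fell by 4.56 on the log2 scale, SYK by 4.22 and the cartilage collagen gene COL2A1 by 2.61. The adjusted p in edgeR's test with Benjamini-Hochberg adjustment was 5.55e-13 for CDKN1A, 3.04e-13 for MDM2, GADD45A and LIF, 1.87e-08 for EPSTI1 and 2.96e-05 for SYK.

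The p53 targets had a median of 3.22 at 144 h of irinotecan (35 higher adjusted over the list alone, camera adjusted p = 7.28e-80, and adjusted p = 0.00865 with an estimated correlation). The NF-kB list (20 higher adjusted over the list alone) and the interferon list (26 higher adjusted over the list alone) had adjusted p = 0.178 and 0.509 with an estimated correlation. Of 32 S-phase genes 23 fell and 1 rose (25 and 1 adjusted over the list alone), MCM3 by 0.66 and MCM5 by 0.79 on the log2 scale, with adjusted p = 0.457 with an estimated correlation. Of 24 cholesterol synthesis genes 20 fell and 3 rose, FDFT1 down, with −1.22, and HSD17B7 up, with 2.07, and the list had adjusted p = 0.125 with an estimated correlation. Of 28 DNA repair genes 15 fell and 1 rose, with RPA1, of the single-strand DNA binding complex, at −0.68, and the list had adjusted p = 0.469 with an estimated correlation. Mitosis genes did not follow: TPX2 rose by 0.59, UBE2C rose by 0.35, a call lost without control replicate 2 or irinotecan 144 h replicate 1 (edgeR adjusted p = 0.0556 and 0.178), and the other 30 of 32 did not pass.

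Of 11 tubulin genes at 144 h of irinotecan 3 fell, TUBB by 0.48, TUBA1B by 0.42 and TUBB4 by 0.66 on the log2 scale, and 1 rose. Of 24 EWS-FLI1 activated genes 8 fell and 7 rose, with the homeobox genes NKX2-2 and HOXD13 at −0.68 and −0.56 and UPP1 at 2.46. Of 13 EWS-FLI1 repressed genes 9 rose and 1 fell, DKK1, a Wnt inhibitor gene, by 3.33, with adjusted p = 0.376 with an estimated correlation. Of 21 neural differentiation genes 11 rose and 2 fell, STMN4 by 6.25, with adjusted p = 0.217 with an estimated correlation. BCL2L1, which encodes the survival protein BCL-XL, rose by 1.64 and BAK1, its proapoptotic partner, by 1.37. They belong to the 10 of 22 apoptosis regulators that rose, with 2 that fell, and the camera call of this list was lost without control replicate 2 or irinotecan 144 h replicates 1 or 3 (adjusted p = 0.0559, 0.0662 and 0.0509) and with adjusted p = 0.14 with an estimated correlation. TOP1 rose by 0.80, CES2 by 1.76 and ABCB1 by 6.19, while TUBB3 at 0.15 and MKI67 at −0.27 did not pass. SLFN11 fell by 0.26 on the log2 scale, a call lost without control replicates 1 or 2 or irinotecan 144 h replicates 2 or 3 (edgeR adjusted p = 0.0548, 0.114, 0.106 and 0.143) and in a fit of only the groups compared (0.0713).

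Beside these, 7 of 10 macrophage markers, all 5 neutrophil markers tested and all 6 keratinocyte markers rose at 144 h of irinotecan, with adjusted p = 0.125, 0.125 and 0.309 with an estimated correlation. ITGAM was at 219 ± 38.7 CPM, CXCR2, a neutrophil chemokine receptor gene, was at least 166-fold higher (0 against 598 counts) and the desmosomal gene DSG3 at least 58.7-fold higher (0 against 211 counts). Of 11 endothelial markers 7 rose and 2 fell, of 12 skeletal muscle markers 8 and 1, of 6 adipocyte markers 3 and 1 and of 15 fibroblast and pericyte markers 6 and 5, lists that camera did not call (adjusted p = 0.412, 0.252, 0.266 and 0.473). CYP4F3 had 2980 counts against 1 (ratio 2488, exact 95% interval 446 to 98296), and SIGLEC5, a sialic acid binding lectin gene of myeloid cells, 2593 against 1 (ratio 2165, 388 to 85535). The 7284 genes nearly silent in controls summed to 1670 ± 458 CPM against 42.7 ± 2.51. Of 24 ribosomal protein genes 18 fell, with adjusted p = 0.466 with an estimated correlation. Of 11 immediate-early genes 8 rose, JUN by 1.79, a list call lost without control replicate 2 or irinotecan 144 h replicates 1 or 3 (camera adjusted p = 0.0559, 0.0872 and 0.147) and with adjusted p = 0.509 with an estimated correlation. In all, 4581 genes rose and 3752 fell, 54.2% of those tested.

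Both drugs together for 144 h lowered nearly the whole mitosis list while the p53 targets had their highest median of the 6 treated groups. CDKN1A was at 3737 ± 366 CPM (SD, n = 3), MDM2 at 2054 ± 263 and TP53INP1 at 201 ± 31.1, with log2 fold changes of 6.70 (SE 0.29), 4.75 (SE 0.17) and 3.95 (SE 0.14). TOP2A fell to 332 ± 64.9 from 898 ± 19.9 CPM, MKI67 to 267 ± 39.5 from 653 ± 20.6 and the tubulin gene TUBA1B to 561 ± 11.1 from 1219.8 ± 48.4. BUB1B, a spindle checkpoint kinase gene, fell by 1.13 and KIF11 by 1.05 on the log2 scale. With edgeR's test and Benjamini-Hochberg adjustment the adjusted p was 2.82e-13 for CDKN1A, 7.05e-14 for MDM2 and TP53INP1, 5.11e-08 for TOP2A, 5.84e-07 for MKI67 and 4.22e-10 for TUBA1B.

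Of 32 mitosis genes 31 fell in the combination at 144 h (31 adjusted over the list alone), with a median of −1.06 and adjusted p = 0.215 with an estimated correlation. Of 32 S-phase genes 29 fell (29 adjusted over the list alone), MCM3 by 1.22 on the log2 scale and MCM5 from 267 ± 5.91 to 109 ± 16.6 CPM, and of 28 DNA repair genes 23 fell and 2 rose (24 and 2 adjusted over the list alone), the helicase gene BLM by 1.25. Both of these lists had adjusted p = 0.147 with an estimated correlation. All 35 p53 targets rose, with a median of 3.63 (camera adjusted p = 1.51e-72, and adjusted p = 0.0118 with an estimated correlation). Of 30 interferon response genes 29 rose (29 adjusted over the list alone), HERC5, an ISG15 ligase gene, by 4.78, and all 20 NF-kB and inflammatory genes rose, LIF by 6.69 and IL8 by 7.32, with adjusted p = 0.412 and 0.215 with an estimated correlation. Of 11 tubulin genes 5 fell and 1 rose, TUBB by 0.90 and TUBB2C by 0.83 on the log2 scale, with adjusted p = 0.388 with an estimated correlation, and TUBB3 stayed at −0.03 and did not pass. Of 24 cholesterol synthesis genes 18 fell and 2 rose, FDFT1 at −1.35, with adjusted p = 0.147 with an estimated correlation.

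Of 24 EWS-FLI1 activated genes at 144 h of both drugs, 9 fell, MYC by 0.91 and NKX2-2 by 0.54 on the log2 scale among them, and 6 rose, UPP1 with 2.40. Of 13 EWS-FLI1 repressed genes 9 rose and 1 fell, a call lost without control replicate 2 (camera adjusted p = 0.0561) and with adjusted p = 0.412 with an estimated correlation. Of 21 neural differentiation genes 13 rose and 2 fell, STMN4 up by 6.30, with adjusted p = 0.147 with an estimated correlation. Of 24 hypoxia genes 12 fell and 4 rose, BNIP3L, a mitophagy receptor gene, at −0.77. The hypoxia call was lost without control replicate 3, combination 144 h replicate 1 or combination 144 h replicate 2 (camera adjusted p = 0.0770, 0.0663 and 0.0900) and with adjusted p = 0.572 with an estimated correlation. FAM163B fell by 2.51 and the glycolytic aldolase gene ALDOC by 2.18 on the log2 scale. TOP1 rose by 0.63, CES2 by 1.85 and ABCB1 by 5.99, and SLFN11 fell by 0.56 on the log2 scale (SE 0.09).

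Beside these, 8 of 10 macrophage markers and all 6 keratinocyte markers rose at 144 h of both drugs, with adjusted p = 0.0981 and 0.215 with an estimated correlation, and ITGAM was at 295 ± 107 CPM. Of 11 endothelial markers 7 rose and 2 fell, of 12 skeletal muscle markers 8 and 1, of 6 adipocyte markers 3 and 1 and of 15 fibroblast and pericyte markers 4 and 3, with no camera call (adjusted p = 0.349, 0.126, 0.131 and 0.846). Of 5 neutrophil markers 4 rose (5 adjusted over the list alone), with CXCR2 at least 262-fold higher (0 against 824 counts), a list call lost without control replicate 2 or combination 144 h replicate 2 (camera adjusted p = 0.0539 and 0.0538) and with adjusted p = 0.147 with an estimated correlation. Of 24 ribosomal protein genes 21 fell (22 adjusted over the list alone), with adjusted p = 0.388 with an estimated correlation. SEMA3E had 7213 counts against 2 (ratio 3436, exact 95% interval 951 to 28379), and the 7284 genes nearly silent in controls summed to 2865 ± 779 CPM against 42.7 ± 2.51. In all, 4925 genes rose and 4339 fell, 60.3% of those tested.

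**Figure D3:**
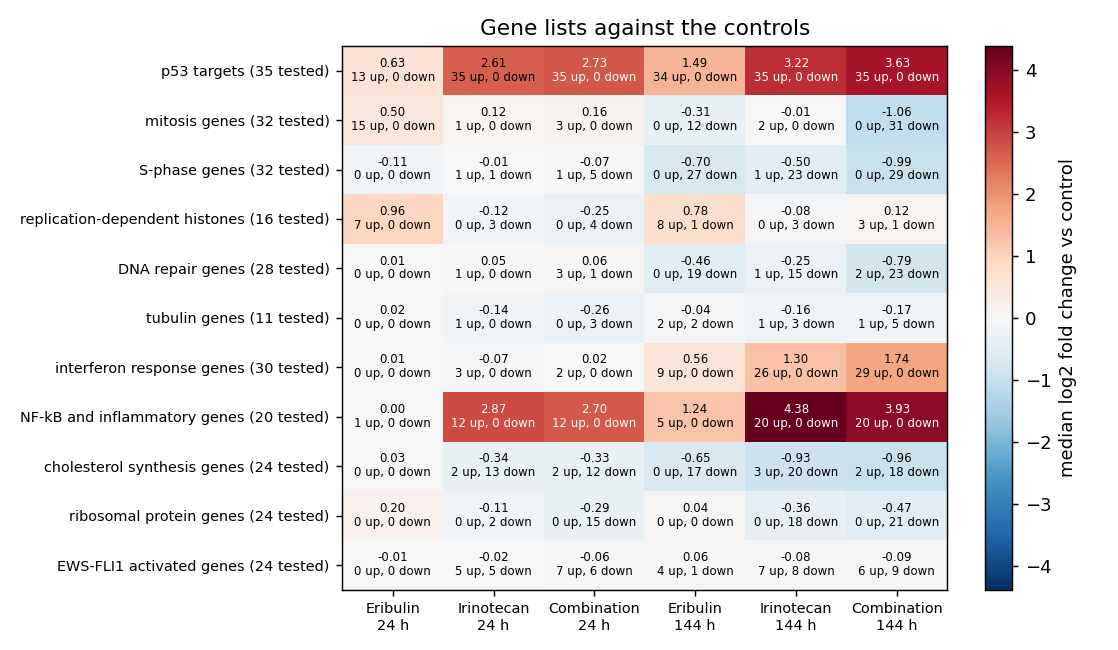
Median log2 fold change against control (color scale and upper number) and numbers of genes called up and down by edgeR (lower line) for 11 gene lists (rows, with the number of genes tested) in the 6 treated groups (columns).

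Adding eribulin to irinotecan for 24 h moved no single gene past the test. Comparing the combination with irinotecan alone at 24 h, edgeR called 0 genes, with 382 at an unadjusted p under 0.05, and DESeq2 called 0, with 368 at an unadjusted p under 0.05. MDM2 was at 968 ± 190 against 791 ± 45.1 CPM (SD, n = 3), a log2 fold change of 0.29 (SE 0.14), TUBA1A had −0.32 (SE 0.10) and TUBB had −0.11 (SE 0.07). By camera, p53 targets lay above other genes with a median of 0.12, neural differentiation genes above with 0.14, and tubulin genes below with −0.06, as did ribosomal protein genes with −0.19, of which RPL7A had −0.20. With an estimated correlation the 4 list calls were lost (adjusted p = 0.899 for p53 targets, 0.49 for neural genes, 0.899 for tubulins and 0.49 for ribosomal proteins). Leaving out irinotecan 24 h replicate 3 ended the p53, tubulin and neural calls (camera adjusted p = 0.225, 0.202 and 0.202), leaving out combination 24 h replicate 3 ended the p53 and tubulin calls (0.600 and 0.770) and leaving out irinotecan 24 h replicate 1 ended the tubulin call (0.289). In simulated data of this comparison, 51.5% of genes changed 1.5-fold and 74.6% of those changed 2-fold were recovered.

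Adding eribulin to irinotecan for 144 h lowered all 32 mitosis genes. UBE2C, which encodes a ubiquitin conjugase of mitotic exit, was at 67.3 ± 5.50 CPM in the combination against 181 ± 31.0 with irinotecan alone (SD, n = 3), a log2 fold change of −1.42 (SE 0.13), and PRC1, a midzone microtubule bundler gene, was at 120 ± 5.16 against 257 ± 36.8. The list had a median of −0.99 (camera adjusted p = 2.74e-61, and adjusted p = 0.0271 with an estimated correlation). TUBA1B was at 561 ± 11.1 against 911 ± 58.8 CPM and TUBB2C at 291 ± 22.8 against 544 ± 35.0. With edgeR's test and Benjamini-Hochberg adjustment the adjusted p was 1.85e-06 for UBE2C, 3.72e-06 for PRC1, 1.87e-05 for TUBA1B and 3.89e-05 for TUBB2C.

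Of 32 S-phase genes 27 were lower in the combination than with irinotecan alone at 144 h (30 adjusted over the list alone), the ribonucleotide reductase gene RRM2 with −0.78, and of 28 DNA repair genes 15 were lower (18 adjusted over the list alone), FANCA with −0.96. Both lists had adjusted p = 0.138 with an estimated correlation. Of 11 tubulin genes 5 were lower and 1 higher (6 and 2 adjusted over the list alone), with adjusted p = 0.352 with an estimated correlation. Of 35 p53 targets 9 were higher (12 adjusted over the list alone), TP53INP1 by 0.84 and ZMAT3, an RNA-binding tumor suppressor gene, by 1.05, with adjusted p = 0.645 with an estimated correlation. ARHGAP28 was higher by 4.27, and NMU, the neuromedin U gene, was lower, with −1.73. Of 30 interferon response genes 4 were higher (2 adjusted over the list alone), and the call turned direction without irinotecan 144 h replicate 2 (camera adjusted p = 0.978) and was lost without combination 144 h replicates 2 or 3 (0.278 and 0.140) and with adjusted p = 0.645 with an estimated correlation. Of 24 hypoxia genes 3 were lower, among them PFKFB4, a regulator of glycolysis, but not in a fit of only the groups compared (edgeR adjusted p = 0.0741), and the list call was lost without irinotecan 144 h replicate 3 (camera adjusted p = 0.0516) and with adjusted p = 0.645 with an estimated correlation. In all, 1340 genes were higher and 1297 lower, and the 2637 calls became 1480 without irinotecan 144 h replicate 1 and 659 in a fit of only the groups compared.

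At 24 h all 35 p53 targets were higher in the combination than with eribulin alone, GADD45A at 493 ± 78.3 against 17.7 ± 2.13 CPM (SD, n = 3), with a list median of 2.05 (camera with an estimated correlation, adjusted p = 0.0149). Of 16 histone genes 13 were lower (15 adjusted over the list alone) and of 32 mitosis genes 14 (17 adjusted over the list alone), calls lost with adjusted p = 0.095 and 0.499 with an estimated correlation. HIST2H2BE was at 4.95 ± 1.11 against 33.9 ± 8.68 CPM, a log2 fold change of −2.77 (SE 0.33), HIST1H1C had −1.55 (SE 0.21) and PTTG1 −0.71 (SE 0.13). In edgeR's test with Benjamini-Hochberg adjustment the adjusted p was 1.16e-06 for HIST2H2BE, 6.32e-06 for HIST1H1C and 0.000186 for PTTG1. Of 24 ribosomal protein genes 22 were lower (24 adjusted over the list alone), with adjusted p = 0.246 with an estimated correlation, beside 4 macrophage, 6 keratinocyte and 8 skeletal muscle markers that were higher, with adjusted p = 0.095, 0.239 and 0.468 with an estimated correlation. The skeletal muscle call was also lost without combination 24 h replicate 3 (camera adjusted p = 0.137). LIF was higher by 4.85 and IL8 by 7.24, and 3184 genes were higher and 1580 lower.

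At 144 h the combination against eribulin alone had 34 of 35 p53 targets higher, with GADD45A at 977 ± 230 against 41.8 ± 4.46 CPM (SD, n = 3), and 27 of 32 mitosis genes lower, with CDC20 at 77.0 ± 14.7 against 212 ± 8.37. BIRC5, which encodes survivin, was at 100.1 ± 6.46 against 199.7 ± 21.9 CPM, and TUBA1B had −0.64 (SE 0.08). With edgeR's test and Benjamini-Hochberg adjustment the adjusted p was 5.96e-12 for GADD45A, 5.74e-07 for CDC20, 1.17e-06 for BIRC5 and 1.55e-06 for TUBA1B. The hypoxia marker CA9 had −2.40 (SE 0.65) and ALDOC −1.79 (SE 0.23), within a hypoxia list of which 15 genes were lower and 3 higher. Of 30 interferon response genes 27 were higher, of 11 tubulin genes 9 lower and 1 higher, and of 24 ribosomal protein genes 23 lower, beside 6 macrophage and 5 keratinocyte markers that were higher. The list calls were lost with an estimated correlation (adjusted p = 0.158 for p53 targets, 0.377 for mitosis genes, 0.493 for hypoxia genes, 0.493 for interferon genes, 0.384 for tubulins, 0.377 for ribosomal proteins, 0.182 for macrophage and 0.414 for keratinocyte markers), that of the keratinocyte markers also without eribulin 144 h replicates 1, 2 or 3 or combination 144 h replicates 1 or 3 (camera adjusted p = 0.0604, 0.0616, 0.0515, 0.0558 and 0.0554). In all, 4243 genes were higher and 3834 lower.

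At 24 h all 35 p53 targets were higher with irinotecan than with eribulin, each given alone, DRAM1 at 134 ± 13.3 against 6.88 ± 1.497 CPM (SD, n = 3), and LIF at 237.7 ± 24.3 against 8.82 ± 2.39. CCNB1, the mitotic cyclin gene, was lower, at 285 ± 10.8 against 562 ± 117, as were HIST2H2BE, with −2.33 (SE 0.32), and HIST1H1C, with −1.78 (SE 0.21). In edgeR's test with Benjamini-Hochberg adjustment the adjusted p was 3.08e-11 for DRAM1, 2.12e-11 for LIF, 0.000384 for CCNB1 and 8.33e-06 for HIST2H2BE. Of 32 mitosis genes 17 were lower (18 adjusted over the list alone) and of 16 histone genes 11 (13 adjusted over the list alone), with adjusted p = 0.45 and 0.123 with an estimated correlation, while the p53 list kept adjusted p = 0.0138 with an estimated correlation. Beside these, 4 macrophage markers were higher, ITGAM at 209.7 ± 33.4 against 1.19 ± 0.187 CPM, and 1 lower, 5 keratinocyte (6 adjusted over the list alone) and 7 skeletal muscle markers were higher and 18 of 24 ribosomal protein genes lower, with adjusted p = 0.136, 0.201, 0.423 and 0.423 with an estimated correlation. In all, 2927 genes were higher and 1099 lower.

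At 144 h irinotecan against eribulin had 33 of 35 p53 targets, 19 of 30 interferon response genes and 18 of 20 NF-kB and inflammatory genes higher, and 14 of 32 mitosis genes higher. GADD45A was at 748 ± 242 against 41.8 ± 4.46 CPM (SD, n = 3), and ARHGAP28 at 0.196 ± 0.111 against 4.56 ± 3.38, with −4.35 (SE 0.83). HIST1H1C had −2.08, among 9 of 16 histone genes that were lower. The edgeR adjusted p after Benjamini-Hochberg adjustment was 1.9e-11 for GADD45A and 0.000244 for ARHGAP28. The p53, NF-kB and histone list calls were lost with adjusted p = 0.221, 0.29 and 0.342 with an estimated correlation, and camera did not call the mitosis (adjusted p = 0.111) and interferon (adjusted p = 0.0689) lists. Of 24 ribosomal protein genes 22 were lower, with adjusted p = 0.387 with an estimated correlation, beside 5 macrophage markers that were higher (adjusted p = 0.221 with an estimated correlation). In all, 4126 genes were higher and 3261 lower.

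With no control of 144 h, comparisons between harvest times also hold any change of untreated tumors. Where irinotecan was given (days 1 to 5) they may hold more doses. All 32 mitosis genes were lower at 144 than at 24 h of eribulin, with a median of −0.80, CDC25C, a mitotic entry phosphatase gene, with −1.07 (SE 0.12) and NDC80, a kinetochore gene, with −1.09. Of 24 cholesterol synthesis genes 18 were lower, with a median of −0.74 and SREBF2, a master regulator of the pathway, with −0.98, while GDF15 was higher by 2.94 and ZMAT3 by 1.89. With edgeR's test and Benjamini-Hochberg adjustment the adjusted p was 2.78e-05 for CDC25C and 5.87e-05 for GDF15. Of 35 p53 targets 29 were higher (32 adjusted over the list alone), and 28 of 32 S-phase and 19 of 28 DNA repair genes lower. These 5 list calls held with an estimated correlation (adjusted p = 0.0142 for p53 targets, mitosis and DNA repair genes, 0.036 for S-phase and 0.00381 for cholesterol synthesis genes). Beside these, 2 macrophage markers and 3 of 11 immediate-early genes (6 adjusted over the list alone) were higher, and camera called ribosomal protein genes lower with no member past edgeR's test, with adjusted p = 0.217, 0.333 and 0.484 with an estimated correlation. The macrophage call was also lost without eribulin 24 h replicates 2 or 3 or eribulin 144 h replicate 2 (camera adjusted p = 0.0531, 0.0525 and 0.0595), and the ribosomal call without the last (0.104). In all, 857 genes were higher and 873 lower, and the 1730 calls became 838 without eribulin 24 h replicate 1 and 1035 without eribulin 144 h replicate 2, and 883 in a fit of only the groups compared.

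From 24 to 144 h of irinotecan, 26 of 30 interferon response genes were higher (28 adjusted over the list alone) and 12 of 20 NF-kB genes, with adjusted p = 0.14 and 0.305 with an estimated correlation. CCL2, a monocyte chemokine gene, was higher by 4.43 on the log2 scale, EPSTI1 by 2.44, the adhesion gene ICAM1 by 2.31 and MDM2 by 0.97, with ARHGAP28 at −4.44 and the developmental regulator SALL1 at −3.69. Of 35 p53 targets 29 were higher (31 adjusted over the list alone), while 26 of 32 S-phase and 15 of 24 cholesterol synthesis genes were lower. Beside these, 3 macrophage and 2 neutrophil markers were higher, the lysozyme gene LYZ by 3.52 and TREM1 by 3.95, as were 5 of 11 immediate-early genes (8 adjusted over the list alone), and 10 of 24 ribosomal protein genes were lower (16 adjusted over the list alone). These lists had adjusted p = 0.14 (p53), 0.14 (S-phase), 0.0732 (cholesterol), 0.196 (macrophage), 0.14 (neutrophil), 0.305 (immediate-early) and 0.305 (ribosomal) with an estimated correlation. The macrophage call was also lost without irinotecan 24 h replicate 1 or irinotecan 144 h replicate 3 (camera adjusted p = 0.0616 and 0.111), the neutrophil call without irinotecan 24 h replicate 1 (0.0616) and the immediate-early call without irinotecan 144 h replicate 3 (0.0623). In all, 1694 genes were higher and 1514 lower, and the 3208 calls became 2088 and 1734 without irinotecan 24 h replicates 2 and 3 and 1227 without irinotecan 144 h replicate 3. The share that was higher, 52.8%, was 44.9% with library size alone and 59.9% with DESeq2's size factors, so that the larger direction turned with the scaling.

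From 24 to 144 h of both drugs all 32 mitosis genes and 31 of 32 S-phase genes were lower, with medians of −1.21 and −0.94. KIF11 had −1.16 (SE 0.10), the mitotic kinase gene AURKB −1.35, RRM2 −1.16 and FANCA −1.40, and of 28 DNA repair genes 23 were lower and 1 higher. OAS2, an antiviral synthetase gene, was higher by 3.83 and ISG15 by 2.41, within 29 of 30 interferon response genes, and 5 macrophage markers were higher, CD163 by 3.32. In edgeR's test with Benjamini-Hochberg adjustment the adjusted p was 1.15e-07 for KIF11, 1.26e-07 for AURKB and 9.9e-06 for OAS2. The mitosis, S-phase and DNA repair calls held with adjusted p = 0.0281 with an estimated correlation, and the interferon and macrophage calls were lost with adjusted p = 0.169. Ribosomal protein genes were lower in 5 of 24 cases, with adjusted p = 0.576 with an estimated correlation. In all, 2729 genes were higher and 2609 lower, 51.1% higher against 48.8% with library size alone and 56.9% with DESeq2's size factors.

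Additivity was tested as the combination minus both single-drug effects on the log2 scale. At 24 h PVRL4 and CDKN1A stood below the sum, with −3.28 (SE 0.53) and −2.03 (SE 0.32), each with an edgeR adjusted p = 0.0304 after Benjamini-Hochberg adjustment. The histone genes as a list had a median of −1.22 (camera adjusted p = 1.72e-20, and adjusted p = 0.0112 with an estimated correlation), p53 targets −0.50, mitosis genes −0.46 and ribosomal protein genes −0.35, these 3 with adjusted p = 0.132 with an estimated correlation. Adjusted over the list alone, 9 histone, 16 p53, 20 mitosis and 16 ribosomal protein genes were below the sum. Camera called fibroblast and pericyte markers above it with a median of 0.23 and skeletal muscle markers with 0.59, no member past edgeR's test, with adjusted p = 0.26 and 0.271 with an estimated correlation. The first call was also lost without control replicate 3, eribulin replicate 1, irinotecan replicates 1 or 3 or combination replicate 2 (camera adjusted p = 0.0896, 0.0612, 0.0590, 0.0649 and 0.182) and the second without combination replicate 3 (0.0622). Over all genes only PVRL4 and CDKN1A passed, both calls were lost without each of 11 of the 12 libraries, leaving 0 calls in edgeR beside 18 in DESeq2 with all libraries and 1197 at an unadjusted edgeR p under 0.05, and there were 7 without eribulin 24 h replicate 1 or without a filter on low counts and 18 in a fit of only the groups compared.

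At 144 h, where a time effect in the untreated tumors would enter with the opposite sign, 480 genes lay above the sum and 751 below it. CDKN1A was below it, with a log2 value of −4.12 (SE 0.33), GDF15 by −5.07, LIF by −2.81, CDC20 by −1.58 and TUBB2C by −0.86. PDGFRB, a pericyte receptor gene, was above it by 1.78. With edgeR's test and Benjamini-Hochberg adjustment the adjusted p was 8.5e-07 for CDKN1A and 0.00106 for CDC20. Of 35 p53 targets 28 were below (31 adjusted over the list alone) and of 24 cholesterol synthesis genes 14 above (15 adjusted over the list alone), both with adjusted p = 0.0182 with an estimated correlation. Of 32 mitosis genes 19 were below (25 adjusted over the list alone), with adjusted p = 0.184 with an estimated correlation, and of 15 fibroblast and pericyte markers 5 above, with adjusted p = 0.0808 with an estimated correlation. Of 11 immediate-early genes 6 were below (10 adjusted over the list alone), with adjusted p = 0.205 with an estimated correlation. The 1231 calls became 675, 477 and 493 without control replicates 1, 2 and 3, 650 without eribulin 144 h replicate 2, 1996 and 480 without irinotecan 144 h replicates 2 and 3, and 759 without combination 144 h replicate 2, and 353 in a fit of only the groups compared.

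The genes called after irinotecan and after the combination were largely shared. At 24 h 2728 genes were higher and 755 lower in both, against 622 and 96.0 for independent lists, and at 144 h 3981 and 2918, against 1468 and 1059. Eribulin and irinotecan alone shared 41 higher and 4 lower genes at 24 h (20.7 and 0.733 for independent lists) and 806 and 642 at 144 h (345 and 239). Of the genes higher at 24 h, 46 of 109 with eribulin and 2779 of 2918 with irinotecan were also higher at 144 h (8.21 and 870 for independent lists). Simulated unchanged groups against the same controls shared between 0 and 0.05 genes on average over 20 simulations, in which hardly any gene is called, so that this value holds no effects and does not measure sharing between lists of this length. The covariance of log2 fold changes across genes was 1.90 for irinotecan and combination at 24 h and 2.79 at 144 h, against 0.0848 and 0.0838 simulated, and 0.178 for eribulin and irinotecan at 24 h and 0.552 at 144 h, against 0.0841 and 0.0838. Part of each excess may come from the shared controls, of which there were too few to split, and genes are not independent replicates.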

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

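The tests of RNA from other cell types, of library depth, of olfactory receptor genes in the combination or nearly silent in controls and of the control harvest time, and the sums over all genes nearly silent in 1 group, were chosen only after the results were seen.

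Between 24 and 144 h, 1730 genes differed with eribulin, 3208 with irinotecan and 5338 with both drugs. These also hold any change of untreated tumors (no control of 144 h) and, where irinotecan was given (days 1 to 5), perhaps more doses. The sum of the single-drug effects on the log2 scale differed from the combination in 2 genes at 24 h and 1231 at 144 h. Leaving out single libraries moved these numbers by over 1.5 times in several cases, each named in its comparison. It gave 838 to 2009 for eribulin and 1227 to 3248 for irinotecan between times, and 477 to 1996 for non-additivity at 144 h. The non-additive genes at 24 h became 7 without eribulin 24 h replicate 1 and 0 in edgeR without each of the other 11 libraries, beside 1197 at an unadjusted p under 0.05 and 18 called by DESeq2 with all libraries. Reads outside annotated genes, which no comparison used, took 16.5% ± 0.773 of uniquely aligned reads in controls (SD, n = 3, highest 17.2%), and every library of 3 groups lay above that: 18.7% ± 0.670 in the combination at 24 h, 19.0% ± 1.31 with irinotecan at 144 h and 20.7% ± 0.834 with both at 144 h.

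Over all 23228 genes, the 7284 with at most 3 counts over the controls summed to 42.7 ± 2.51 CPM in controls and 1670 ± 458 with irinotecan at 144 h (SD, n = 3), while the 5822 with at most 3 counts over those irinotecan libraries summed to 34.5 ± 1.44 there and 36.1 ± 2.38 in controls. Of the former, 542 passed the filter on low counts, which admits them only through higher counts in treated groups, and were called higher, so that their sum of 177 times the control gives the size of a rise they were chosen for. Background reads stay open: the 390 olfactory receptor genes, which the tumor should not use, summed to 2.37 times the control with irinotecan at 144 h and 4.24 times with both drugs, and the 380 of them nearly silent in controls to 32.3 and 71.6 times, near the 39.1 and 67.0 times of the other 6904, although fewer of the 380 had over 3 counts (5.26% and 7.89%, against 23.3% and 27.7%). Of 12 abundant macrophage or keratinocyte transcripts 1 reached ITGAM or FLG: KRT10, already at 24.2 CPM in controls. With irinotecan at 144 h TYROBP stood at 0.00982 and CD14 at 0.611 CPM against 219 for ITGAM. Such cells would be of the mouse, whose reads on human genes were not tested, so their RNA stays open. Depth is argued against by counts thinned to 15.05 M per library, where 17435 ± 87.1 genes were detected with irinotecan at 144 h against 16216 ± 32.1 in controls. Over the 542 genes, chosen for that rise, the lowest thinned irinotecan library had 111 times the highest control. This ratio does not test depth. Reads from mouse cells stay open too, beside a response of the tumor cells.

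The 1231 non-additive genes at 144 h may hold a change of untreated tumors between 24 and 144 h, which enters this contrast with the opposite sign. With no control of 144 h this cannot be told apart from an interaction of the drugs on the log2 scale. Of 50 drawn splits of the 12 libraries, 4 gave as many genes, the highest other 4836, and at 24 h 3 of 50 gave at least 2, the highest other 2145. By the bound set in advance chance fits both and is not excluded, but the splits mix libraries with and without irinotecan. Splits that call several times the real number point to that structure of the samples, and the first principal component, with 74.4% of the variance, set the libraries with irinotecan apart from the others.

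In each of the other 15 comparisons the 10 splits are too few for a share under 0.05. In 14 of them 1 split, the real one, gave as many genes. The highest number of the other splits was 85 for the combination against irinotecan at 144 h (real 2637). It was 432 for irinotecan against eribulin at 144 h (real 7387) and 1 for both drugs between harvest times (real 5338). In the rest it was 0, with real numbers from 121 to 9264. For the combination against irinotecan at 24 h edgeR called 0 genes in the real split and in all 10, with 382 at an unadjusted p under 0.05 in the real one and 0 called by DESeq2.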

How the results depend on the processing

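The alternative chosen only after seeing the data was the covariance over genes with a mean log2 CPM of at least 3. The cause of the differences below was not tested, except that a fit on fewer libraries or a 2-fold minimum changes how many genes can pass. Replicate pairs had a chi-square per degree of freedom of 3.45 to 5.01 in controls. It was 19.9 to 37.1 with irinotecan and 21.1 to 34.4 with both drugs at 144 h. The main fit pools spread over groups, so its p-values between 144 h groups may be too small. With DESeq2's size factors and with library size alone, all 23 numbers of called genes stayed within 1.5 times. DESeq2 called 281 higher and 94 lower genes for eribulin at 24 h, and 18 non-additive genes at 24 h. Without a filter on low counts there were 7 non-additive genes at 24 h. Fitting only the groups compared gave 502 higher and 271 lower genes for eribulin at 24 h, 2492 lower for irinotecan and 2811 lower for the combination at 24 h, 659 for the combination against irinotecan at 144 h, 883 for eribulin between times, and 18 and 353 non-additive genes at 24 and 144 h.

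Leaving out each library in turn gave 11 to 133 higher and 0 to 11 lower genes for eribulin at 24 h, 377 to 626 lower for irinotecan and 815 to 1152 lower for the combination at 24 h, and 581 to 1070 higher and 553 to 911 lower for eribulin at 144 h. It gave 1480 to 2759 for the combination against irinotecan at 144 h, 838 to 2009 for eribulin and 1227 to 3248 for irinotecan between times, and 0 to 7 and 477 to 1996 non-additive genes at 24 and 144 h. Each library that moved a number of called genes by over 1.5 times is named beside it in the comparisons. The counts of 0 are edgeR's, and with all libraries 2144 (eribulin at 24 h) and 1197 (non-additive at 24 h) genes had an unadjusted p under 0.05, and DESeq2 called 94 lower and 18. Named genes lost their call in 220 of 3462 such fits and gained it in 13. Precision limits small non-additive effects: in simulated data 33.0% and 31.8% of 1.5-fold changes were recovered at 24 and 144 h, against 40.3% to 63.6% in the 6 comparisons with control, but 67.7% and 60.7% of 2-fold (against 65.7% to 79.1%) and 84.8% and 83.3% of 4-fold changes (83.3% to 92.4%).

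With a 2-fold minimum, eribulin shared 15 higher and 0 lower genes with irinotecan at 24 h and 15 and 0 with the combination, and irinotecan and the combination shared 1568 and 14. At 144 h the same pairs shared 293 and 26, 313 and 32, and 2275 and 172. Between 24 and 144 h, 23 and 0 were shared for eribulin, 1597 and 17 for irinotecan and 1701 and 32 for both. Over all genes, leaving out single libraries gave irinotecan at 24 h a mean Spearman correlation of gene length with change of 0.0364 to 0.0719. It was 0.0364, 0.0599 and 0.0719 without control replicates 1, 2 and 3. Over genes with a mean log2 CPM of at least 3 all libraries gave 0.0446, and −0.248 for eribulin. Over those genes the covariance of fold changes was 0.0333 to 0.638 over the 9 pairs of comparisons, beside 0.0101 to 0.0103 in simulation.

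With an estimated correlation 152 of 442 list results lost their call. Calls that held were p53 targets in all 6 comparisons against control, in irinotecan and combination against eribulin at 24 h, in eribulin between times and in non-additivity at 144 h; histones for eribulin and for non-additivity at 24 h; S-phase and DNA repair for eribulin at 144 h and, with mitosis, for eribulin and both drugs between times; mitosis for the combination against irinotecan at 144 h; and cholesterol synthesis for eribulin at 144 h and between times, and for non-additivity at 144 h. With fry 29 lost it, 103 gained it and 3 turned direction: integrated stress (adjusted p = 0.0278, range over alternatives 0.0278 to 0.996) and EWS-FLI1 activated genes (0.0155, range 0.0155 to 0.939) for the combination against eribulin at 24 h and EWS-FLI1 activated genes (0.0221, range 0.0221 to 0.927) for irinotecan against eribulin at 24 h. The interferon list of the combination against irinotecan at 144 h turned without irinotecan 144 h replicate 2 (0.978, range 6.53e-07 to 0.978) and lost its call without combination 144 h replicates 2 and 3 (0.278 and 0.140). The mitosis list of the combination against irinotecan at 24 h turned without combination 24 h replicate 2 (0.0226), and leaving out single libraries gave from 5.66e-05, without combination 24 h replicate 3, to 0.882, without irinotecan 24 h replicate 2.

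With the replicate number as a block the non-additive genes at 24 h became 0 in edgeR, with 1100 at an unadjusted p under 0.05, and the other 22 numbers of called genes stayed within 1.5 times. Correlations of same-numbered libraries ranged from −0.288 to 0.278 and 3 of 21 libraries lay closest to their own number, so that the numbers do not pair the samples.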

Other observations

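No test in this part was chosen after its result was seen, but the lists in the first account were picked for description after their values were known.

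Between 24 and 144 h of both drugs, 7 of 20 mesenchymal genes were higher (7 adjusted over the list alone), TGFB2, a transforming growth factor gene, at 378 ± 58.8 against 239 ± 16.2 CPM (SD, n = 3) and MMP9, a gelatinase gene, at 83.0 ± 13.9 against 14.6 ± 3.44. Camera gave the list an adjusted p = 0.0233, which became 0.0697 without combination 24 h replicate 3 and 0.0530 without combination 144 h replicate 2 (range over alternatives 0.00176 to 0.282), and the adjusted p = 0.282 with an estimated correlation. Between 24 and 144 h of irinotecan, 6 of 21 integrated stress and unfolded protein response genes were higher and 1 lower (6 and 1 adjusted over the list alone), with SLC7A11, a cystine transporter gene, at 19.5 ± 3.01 against 7.65 ± 0.0611 CPM, and 7 of 22 apoptosis regulators were higher and 1 lower (8 and 1 adjusted over the list alone), with MCL1, a survival gene of the BCL2 family, at 689 ± 125 against 414 ± 20.3. Camera gave an adjusted p = 0.00654 and 0.00706 for these lists, and adjusted p = 0.140 and 0.0732 with an estimated correlation (ranges over alternatives 0.00101 to 0.140 and 0.000115 to 0.0732). The adjusted p of the 4 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000185 for TGFB2, 0.000239 for MMP9, 0.000441 for SLC7A11 and 0.000796 for MCL1.

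Topoisomerase I inhibition is known to lower long transcripts, and the mean Spearman correlation across genes of length and log2 change was predicted to be below 0 after 24 h of irinotecan. Over 14583 genes it was 0.0564 ± 0.00313 (SD, n = 3), against −0.163 ± 0.0811 with eribulin and −0.00511 ± 0.121 in controls, so that the prediction was not met. This argues against a lowering larger than the spread of the controls, and a smaller one is not excluded, since the controls ranged from −0.140 to 0.0934 (exact permutation p = 0.7 against them). The difference from eribulin was 0.219, with an exact permutation p = 0.1, the smallest that 3 against 3 allow. Genes are not independent replicates.

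Whether eribulin moved the same genes on top of irinotecan was tested across the genes called with eribulin alone. At 24 h the Pearson correlation of their changes was 0.0883 over 121 genes (−0.0228 to 0.205 leaving out each of 12 libraries), with 92 in the same direction, and at 144 h 0.401 over 2137 genes (0.283 to 0.532), with 1491 in the same direction. On top of irinotecan itself, 0 of the 121 were called at 24 h in edgeR, where 382 of all genes had an unadjusted p under 0.05 and DESeq2 called 0, and at 144 h 531 of the 2137 were called in the same and 55 in the opposite direction. Neither met the bounds set in advance, so that the question stays open at both times.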
